A study of Mus musculus with 3 samples.

How the data were processed

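Liver and spleen of the mouse were compared on 3 two-colour arrays of one dye orientation. The labels name spleen as the Cyanine-3 channel and liver as the Cyanine-5 channel, and describe commercial total RNA from which cRNA was made by single-round amplification. The array titles number the arrays 1 to 3, and these numbers are used as replicate numbers.

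The values used were the processed table deposited by the authors, with 1 log2 ratio per probe and array. The scale, background correction, normalization, scanner software and genome build are not given in the sources used here. The base of the logarithm was read from the values: the highest value, 6.64 on array 3, was shared by 3 probes and equals the log2 of 100, a fold at which scanner software can cut off ratios. The direction of the ratio was taken as likely liver over spleen, from the dyes. The median of the deposited log2 ratios was 0 on each array with all values, and -0.02, -0.00237 and 0.03 on arrays 1, 2 and 3 without exact zeros.

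Exact zeros filled 23.7% of the values of array 1, 20.6% of array 2 and 29.6% of array 3, while only 137, 127 and 79 other values lay within 0.01 of 0. Pearson's r between arrays 1 and 3 was 0.873 with the zeros kept and 0.972 over the probes with a ratio on both. A zero was therefore treated as no ratio, a choice made after the values were seen, and keeping the zeros was added as an alternative. Probes with a ratio on all 3 arrays were tested (10173), and 6100 were left out, 2462 of them with zeros on all arrays. The zeros remove some genes with large ratios, which limits the lists. No value column was left without a sample. Control spots could not be told from other unnamed probes.

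Probe names came from the platform annotation supplied with the table: 12336 probes had 1 gene, 61 had several and were left unnamed, and 3876 had none. Symbols were checked through their gene identifiers against a RefSeq gene table of the mouse, which held 12228 of the 12336, and no symbol changed. That table served only for names, since the build behind the probes is not stated, and no coordinates are given. Repeated spots of one probe were to be averaged, but the table gives only row identifiers, so each row counted as 1 probe, and 1 value per accession was added as an alternative. For the named genes, probes of a gene were averaged per array, over 5510 genes. Of 1429 genes with 2 or more tested probes, 153 had probes called in opposite directions.

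The test was limma's moderated test of the mean log2 ratio against 0 (lmFit with an intercept, eBayes; limma 3.58.1, R 4.3.3) with Benjamini-Hochberg adjustment at 0.05, once over probes and once over genes. A count that also asks for a 2-fold difference is given beside it. Gene lists were tested with camera from limma, two-sided, with a preset correlation of 0.01, for the 22 of 26 lists with at least 5 measured genes, adjusted over those lists. On simulated data with the spread of the real 10173 probes, the test for liver against spleen recovered 46% of probes changed by 0.5 log2 units. It recovered 80% of those changed by 1, 96% of those changed by 2 and 98% of those changed by 4, with 5.88% false calls among all calls. Only 50 probes were changed at each size, while 80.8% of the real probes passed. The share changed affects the cutoff of the adjustment, so these percentages need not hold for the real data. No dye bias was simulated.

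The lists, the design and the rule for named genes were fixed before the data were examined. The rule names the 6 genes with the highest and the 6 with the lowest mean among those past the threshold with one sign on all arrays, in each list the 2 such genes with the largest change and the 1 with the largest change against the list's majority, and the housekeeping genes Actb, Gapdh, Hprt and Tbp where measured. One list symbol, G6pc1, was matched through its older form, and 2 list symbols had no match. Alternatives were subtraction of array medians, scaling of the arrays to one spread, each array left out, robust variance moderation, probes with ratios on at least 2 arrays, 1 value per gene, removal of the 10% of probes with the largest SD, limma's treat against 2-fold, and for lists an estimated correlation, ranks, and the probe with the smallest SD. Added after the data were seen were zeros kept as values and 1 value per accession. Fisher's exact tests used scipy 1.17.1.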

Results

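Gene expression in mouse liver and spleen was compared on 3 two-colour microarrays. Each array received spleen material labelled with Cyanine-3 and liver material labelled with Cyanine-5, both amplified in a single round from commercial total RNA. Each array therefore measured both tissues at once, and its log2 ratio is one paired measurement of liver against spleen. The labels give all arrays the same 2 catalogue RNAs and do not say whether tubes, lots or animals differed. The p-values below therefore measure the spread between these arrays, which may be technical. Both dyes kept the same tissue on every array, so a dye bias of a probe was not separable from a tissue difference. The table held 16273 probes. A ratio other than exactly 0 was listed for 12421 probes on array 1, 12921 on array 2 and 11462 on array 3, and 10173 probes had one on all 3 arrays. Spot intensities were not used here, and the number of arrays limits the precision.

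The main comparison asked which genes differ between liver and spleen. Of the 10173 probes tested, 8221 (80.8%) passed an adjusted p of 0.05 in limma's moderated test with Benjamini-Hochberg adjustment, 4173 of them higher in liver and 4048 higher in spleen. Requiring a 2-fold difference as well left 3191 probes (31.4%), of which 1689 were higher in liver and 1502 higher in spleen. Averaged per gene, 5510 named genes were tested, 2254 were higher in liver and 2181 were higher in spleen. Differences of at least 16-fold were found for 59 genes higher in liver and 16 higher in spleen. Values below are mean log2 ratios of liver over spleen ± SD with n = 3 arrays, so that positive values are higher in liver. The base of the logarithm was read from the values and is not stated in the labels. This direction is the likely one: it follows from the dyes in the labels and the usual red-over-green ratio. As a check of this direction, the 8 hepatocyte plasma protein genes had medians of 4.75, 4.96 and 5.37 on arrays 1, 2 and 3. The direction of that list is for this reason no independent result.

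The 3 arrays gave close ratios for the same probe. Pearson's r across the 10173 probes was 0.993 between arrays 1 and 2, 0.972 between arrays 1 and 3 and 0.980 between arrays 2 and 3, with probes not being independent replicates. The SD over arrays of a probe had a median of 0.10 log2 units, and 88.3% of probes had one sign on all arrays against 25% expected by chance. The median of the mean ratios over all probes was 0.01.

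The 6 genes with the highest ratios towards liver were Baat, which conjugates bile acids (6.34 ± 0.12, 81.3-fold), Gldc of the glycine cleavage system (6.33 ± 0.28), the esterase Aadac (6.32 ± 0.28), the sulfotransferase Sult1d1 (6.16 ± 0.18), the organic cation exporter Slc47a1 (6.07 ± 0.43) and the plasma glycoprotein gene Apoh (5.83 ± 0.51, 56.9-fold). On array 3, Gldc and Aadac lay at the highest value of the table, 6.64 or 100-fold, so their means may be cut short by a limit on the ratio. The adjusted p values of these 6 genes lay between 1.40e-05 and 3.60e-05. All 8 measured genes for hepatocyte plasma proteins were higher in liver, at a median of 5.05 (camera adjusted p = 0.000428; adjusted p = 0.352 with an estimated correlation), among them Apoc3, an apolipoprotein of triglyceride-rich particles (5.80 ± 0.28). The coagulation gene F11 (5.58 ± 0.46) was the 1 measured member of the complement and coagulation list. All 4 measured hepatic transporters and transcription factors were higher in liver, including the xenobiotic receptor Nr1i2 (4.17 ± 0.23) and the sterol exporter subunit Abcg8 (3.91 ± 0.27). 

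**Figure D1:**
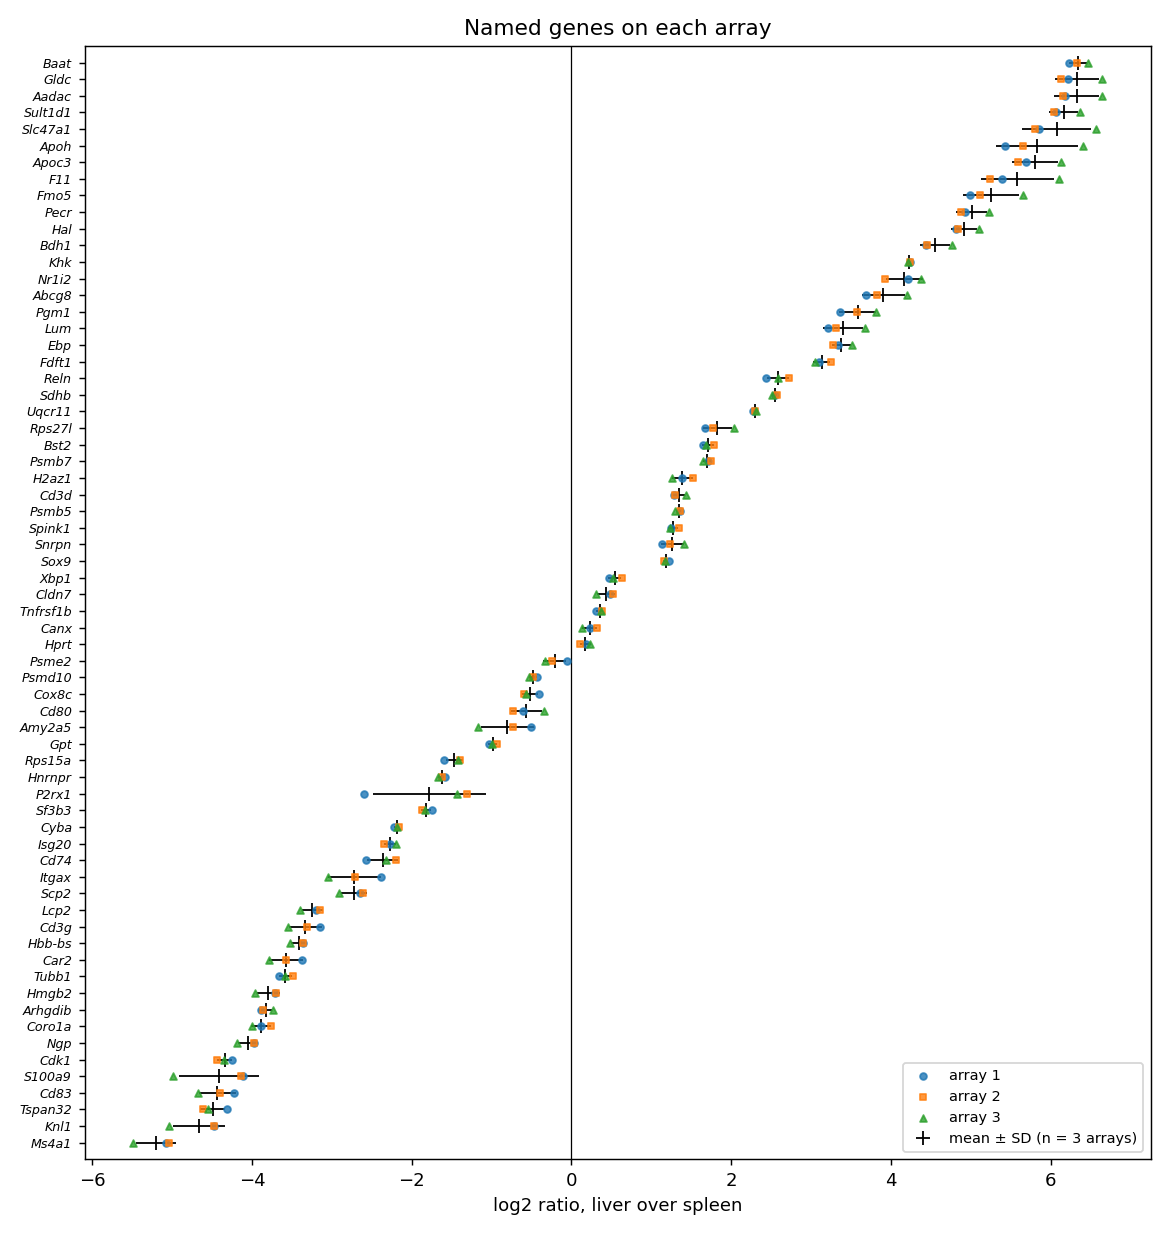
Log2 ratio of liver over spleen (x axis) on each of the 3 arrays for the 66 genes named by the rule (y axis), with the mean and SD over arrays as a tick and bar. The means ran from 6.34 for Baat to -5.20 for Ms4a1, Gldc and Aadac lay at the highest value of the table on array 3, and the arrays lay close together for most genes, with P2rx1 (SD 0.71) the widest.

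In xenobiotic and steroid metabolism, 6 of 7 measured genes were higher in liver (median 3.99, camera adjusted p = 0.00141; adjusted p = 0.352 with an estimated correlation), led by Baat and the flavin monooxygenase Fmo5 (5.25 ± 0.35), and Gstz1 at 0.11 did not pass. A probe of Gstz1 left out for a zero on array 1 read 3.13 and 3.26 on arrays 2 and 3, and Gstz1 was singled out after its values were seen. In amino acid and urea metabolism, 12 of 14 were higher in liver (median 3.18, camera adjusted p = 0.000268; adjusted p = 0.352 with an estimated correlation), led by Gldc and the histidine ammonia-lyase gene Hal (4.92 ± 0.16), while the aminotransferase gene Gpt was higher in spleen (-0.99 ± 0.05). All 5 genes of gluconeogenesis and carbohydrate metabolism were higher in liver (median 3.14, camera adjusted p = 0.00242, and adjusted p = 0.352 with an estimated correlation). Among them were ketohexokinase, Khk (4.23 ± 0.01), and phosphoglucomutase, Pgm1 (3.58 ± 0.23). The 2 Khk probes read 4.50, 4.54 and 4.81 against 3.99, 3.93 and 3.62 on arrays 1, 2 and 3. They moved in opposite directions, so the SD of their average understates the spread of each probe. In fatty acid oxidation and the peroxisome, 13 of 15 genes were higher in liver (median 1.90, camera adjusted p = 0.000834; adjusted p = 0.352 with an estimated correlation), led by Pecr, an enoyl-CoA reductase (5.01 ± 0.19), and Bdh1, which converts ketone bodies (4.55 ± 0.19). The 2 others, Scp2 (-2.72 ± 0.17) and Fabp1 (-0.69 ± 0.08), were higher in spleen. Every tested spot of both was named through expressed sequence tags, and Fabp1 was singled out after its values were seen. All 7 sterol synthesis genes were higher in liver (median 2.92, camera adjusted p = 0.00148; adjusted p = 0.352 with an estimated correlation), including Ebp (3.38 ± 0.12) and squalene synthase, Fdft1 (3.13 ± 0.11).

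At camera's preset correlation, genes of the mitochondrial respiratory chain formed the list with the smallest p. Of 49 measured members, 46 were higher in liver and 41 of these at least 2-fold, at a median of 1.70 (camera adjusted p = 1.26e-10; adjusted p = 0.352 with an estimated correlation). Sdhb, an iron-sulfur subunit of succinate dehydrogenase (2.54 ± 0.03), and Uqcr11 of complex III (2.30 ± 0.02) led the list, and Cox8c was higher in spleen (-0.52 ± 0.10). Atp5b, Atp5l and Cox6a1, counted as higher in liver by their mean over probes, had probes called in both directions. Among 19 proteasome subunits, 15 were higher in liver and 2 in spleen (median 0.76, camera adjusted p = 0.00346; adjusted p = 0.372 with an estimated correlation), with Psmb7 (1.70 ± 0.05) and Psmb5 (1.34 ± 0.03) highest and Psmd10 at -0.48 ± 0.05. Psmd9, counted as higher in liver, and Psmd5, not called, had probes called in both directions.

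Of the lists, B cell genes had the lowest median ratio. Of 13 measured genes of B cells and plasma cells, 12 were higher in spleen, 11 of them at least 2-fold, at a median of -3.31 (camera adjusted p = 0.000268; adjusted p = 0.352 with an estimated correlation). Among tested genes past the threshold with one sign on all arrays, Ms4a1, which encodes the B cell antigen CD20, had the lowest mean (-5.20 ± 0.25, 36.7-fold). The activation marker Cd83 followed in the list (-4.44 ± 0.23), and Xbp1, a factor of secretory cells, was higher in liver (0.54 ± 0.08). The other genes among the 6 lowest were the kinetochore gene Knl1 (-4.67 ± 0.33), the blood cell tetraspanin Tspan32 (-4.49 ± 0.16), S100a9, abundant in neutrophils (-4.42 ± 0.50), and the mitotic kinase gene Cdk1 (-4.34 ± 0.09). The value of Tspan32 rests on 1 probe, and another, left out for a zero on array 1, read -0.40 and -0.09 on arrays 2 and 3. Of 9 genes of T cells and NK cells, 7 were higher in spleen (median -1.87, camera adjusted p = 0.0357; adjusted p = 0.352 with an estimated correlation), led by Cd3g of the T cell receptor complex (-3.33 ± 0.21) and the adaptor Lcp2 (-3.25 ± 0.13). Cd3d, of the same complex as Cd3g, was higher in liver (1.34 ± 0.09). So was Il2rb (0.52 ± 0.06), which did not rest on expressed sequence tags alone and was singled out after its values were seen. Of the 66 named genes, 9 were tested only on probes named through expressed sequence tags: Cd3d, Scp2 and H2az1, which went against their list, and Cd3g, Lcp2, Cdk1, S100a9, Itgax and P2rx1, which went with it. Of 15 genes of lymphocyte and leukocyte signalling, 13 were higher in spleen (median -2.46, camera adjusted p = 0.000662; adjusted p = 0.352 with an estimated correlation), led by the actin regulator Coro1a (-3.88 ± 0.12) and Arhgdib (-3.83 ± 0.08), and Tnfrsf1b was higher in liver (0.35 ± 0.04). The 3 measured genes of MHC class II presentation were higher in spleen, among them the invariant chain Cd74 (-2.36 ± 0.20) and the costimulator Cd80 (-0.56 ± 0.20).

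All 9 macrophage and monocyte genes were higher in spleen (median -1.97, camera adjusted p = 0.000784; adjusted p = 0.352 with an estimated correlation), led by the integrin Itgax (-2.72 ± 0.33) and the NADPH oxidase subunit Cyba (-2.19 ± 0.03), and 1 of them, Fcgr1, had probes called in both directions. All 5 granulocyte genes were higher in spleen (median -1.47, camera adjusted p = 0.0109; adjusted p = 0.383 with an estimated correlation), with S100a9 and the neutrophil granule gene Ngp (-4.05 ± 0.12) lowest. All 5 platelet and megakaryocyte genes were higher in spleen (median -1.70, camera adjusted p = 0.0109; adjusted p = 0.352 with an estimated correlation), including the platelet tubulin Tubb1 (-3.58 ± 0.09) and the ATP receptor P2rx1 (-1.78 ± 0.71, adjusted p = 0.00424). Of 15 erythroid genes, 13 were higher in spleen (median -1.87, camera adjusted p = 0.000317; adjusted p = 0.352 with an estimated correlation), with carbonic anhydrase, Car2 (-3.58 ± 0.21), and the beta-globin gene Hbb-bs (-3.42 ± 0.10 over 8 probes) lowest. Some globin genes are near-identical copies of one another, so probes of those genes may share transcripts. The heme synthesis genes Fech (-0.0003) and Urod (0.11), named after their values were seen, did not pass. The platelet list did not pass with the least variable probe of each gene (adjusted p = 0.0807).

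In the list of cell cycle and DNA replication, 27 of 31 genes were higher in spleen, 20 of them at least 2-fold, at a median of -2.38. Camera gave an adjusted p of 6.42e-06, and 0.352 (unadjusted 0.0303) with an estimated correlation, which was -0.016. The adjusted 0.352 was shared by lists with an unadjusted camera p from 0.0303 to 0.240, so it does not rank them. In the cell cycle list, Cdk1 and the chromatin protein gene Hmgb2 (-3.80 ± 0.15) were lowest, and 3 genes were higher in liver. The highest was the histone variant H2az1 (1.39 ± 0.13), whose 4 probes were named through 1 expressed sequence tag. Mcm4, another of the 3 (0.90 ± 0.13), was singled out after its values were seen. It had probes left out for zeros whose listed ratios had means from -0.25 to -0.18. Of 60 ribosomal protein genes, 53 were higher in spleen and 6 in liver, at a median of -0.72 (camera adjusted p = 3.93e-07; adjusted p = 0.372 with an estimated correlation). Rps15a was lowest (-1.47 ± 0.11) and Rps27l highest (1.83 ± 0.18). Rpl27a (2.26 and -0.54), Rpl32 (1.22 and -0.91) and Rpl35a (1.96 and -0.53), counted as higher in liver by their mean over probes, had probes called in both directions, as had Rpl37a, Rpl39 and Rpl7a, counted as higher in spleen. Of 35 splicing factor genes, 26 were higher in spleen and 3 in liver (median -0.63, camera adjusted p = 0.000266, and adjusted p = 0.352 with an estimated correlation). Sf3b3 (-1.82 ± 0.06) and Hnrnpr (-1.62 ± 0.04) were lowest and Snrpn was highest (1.26 ± 0.14). The 2 Snrpn probes differed, at 1.77, 1.89 and 2.07 against 0.50, 0.59 and 0.76 on arrays 1, 2 and 3.

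**Figure D2:**
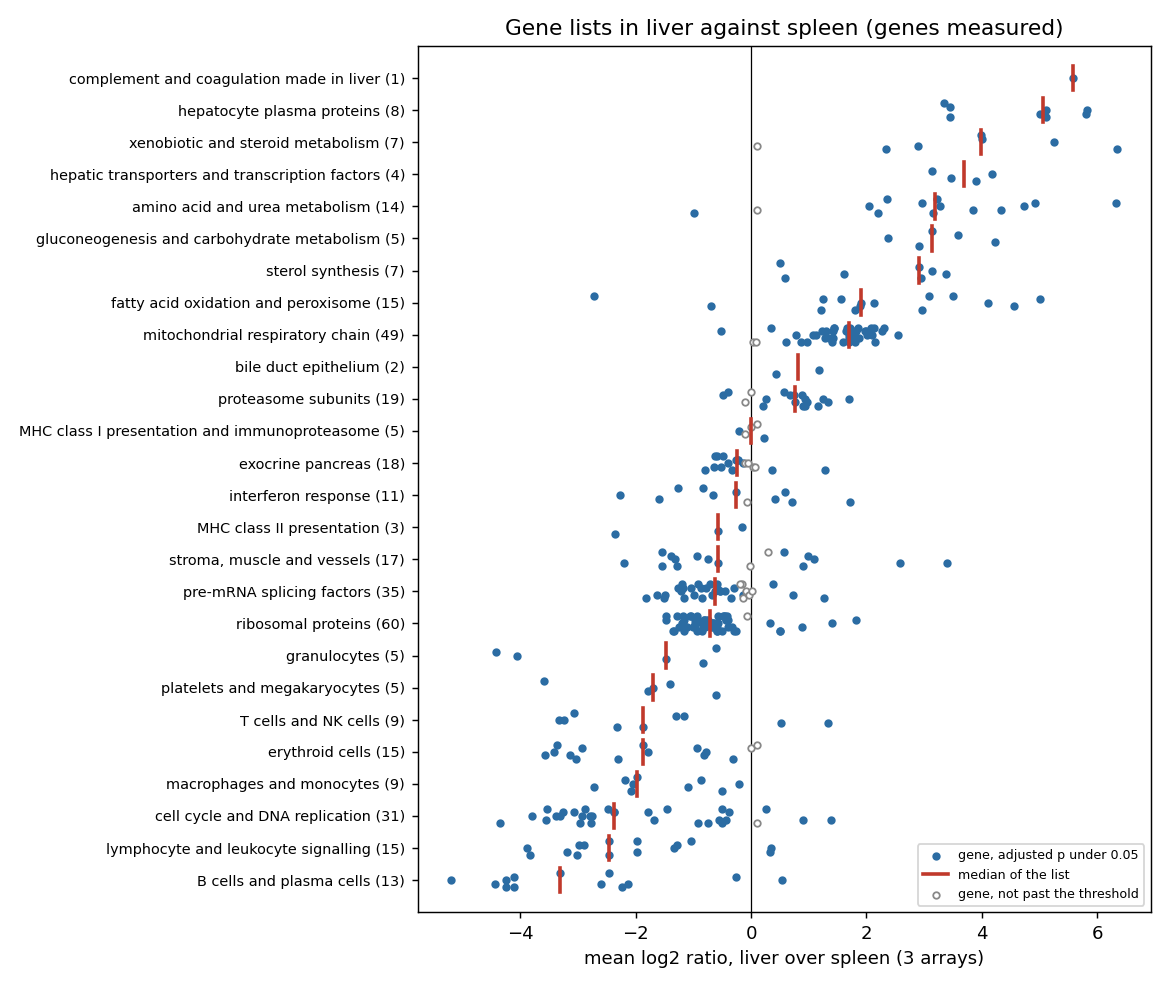
Mean log2 ratio of liver over spleen over 3 arrays (x axis) for the measured genes of each of the 26 lists (y axis, number of genes in parentheses). Filled points passed an adjusted p of 0.05, open points did not, and the red bar is the list's median, from 5.58 for complement and coagulation with 1 gene to -3.31 for B cells and plasma cells.

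For 4 lists the camera test found no shift against the other genes. The 5 genes of MHC class I presentation had a median of -0.01 (camera adjusted p = 0.999): Canx was higher in liver (0.23 ± 0.09), Psme2 was higher in spleen (-0.21 ± 0.14), and adjusted over the list alone neither passed. The adjusted p of Canx was 0.0766 without array 1 and 0.119 without array 2, and that of Psme2 was 0.196 without array 2 and 0.0738 without array 3. Interferon response genes went both ways, 4 of 11 higher in liver and 6 in spleen (median -0.26, camera adjusted p = 0.338), with Isg20 (-2.27 ± 0.07) and Bst2 (1.71 ± 0.07) at the ends. Genes of stroma, muscle and vessels also went both ways, 6 of 17 higher in liver and 9 in spleen (median -0.58, camera adjusted p = 0.455). There the small proteoglycan gene Lum (3.40 ± 0.25) and the extracellular protein gene Reln (2.58 ± 0.14) were higher in liver. Exocrine pancreas genes, included since the pancreas lies beside the spleen, had a median of -0.25, with 12 of 18 higher in spleen, none of them 2-fold (camera adjusted p = 0.0710). Without array 2 the list passed (adjusted p = 0.0462), as it did with zeros kept as values (adjusted p = 0.0348). The amylase gene Amy2a5 was the lowest of these (-0.80 ± 0.33) and the trypsin inhibitor gene Spink1 the highest (1.27 ± 0.06). Both measured bile duct genes, Sox9 (1.18 ± 0.03) and Cldn7 (0.44 ± 0.11), were higher in liver. A probe of Ehf, also on that list, was left out for a zero on array 3. It read -1.22 and -1.27 on arrays 1 and 2, towards spleen, and was singled out after its values were seen. Of the housekeeping genes only Hprt had a ratio on all arrays (0.18 ± 0.06, adjusted p = 0.0259), and its adjusted p was 0.114 without array 1 and 0.0840 without array 2. Adjusted over the list alone, the number of genes called in each direction was the same as over all genes in each of the other 25 lists.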

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

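The tests chosen only after the result was seen were both tests of the zeros, the comparison of the liver and spleen sides of array 3, and the test of sequence tags among genes that went against their list.

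A strong signal lay in probes outside the main test. Among the 2647 probes with a zero on 1 array, 546 (20.6%, Wilson 95% interval 19.1 to 22.2, which covers counting error only) were at least 2-fold with one sign on the other 2 arrays, 271 higher in liver and 275 in spleen. This compares with 31.4% of the probes tested. They included the fibrinogen gene Fgb (5.73 and 6.28 on arrays 2 and 3 for 1 probe, 2.29 and 2.46 for another), Gnmt (5.76 and 6.13 on arrays 1 and 3), Cyp2c37 (5.10 and 5.95 on arrays 2 and 3), the bile acid receptor Nr1h4 (4.20 and 4.60 on arrays 1 and 3) and the immunoglobulin gene Ighm (-3.76 and -4.54 on arrays 2 and 3), all chosen after their values were seen. Some left-out probes of list genes went against their list: the erythroid gene Alas2 (1.09 and 1.23), the B cell gene Spib (0.98 and 1.72) and a probe of Cdk4 (1.95 and 2.51), which by its tested probes was at -0.55. Transthyretin, Ttr, had a ratio on array 3 alone (5.69).

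The zeros themselves follow a pattern. Globin and hepatocyte plasma protein probes, of very abundant transcripts, had a zero on at least 1 array in 56.2% of 89 cases against 35.6% of the other named probes (two-sided Fisher's exact p = 8.77e-05, odds ratio 2.32, 95% interval 1.49 to 3.62; globins alone 57.8%, p = 0.000353; plasma proteins alone 52.0% of 25, p = 0.0978). Ribosomal protein probes, abundant in both tissues, had one in 12.9% of 233 cases against 36.2% (Fisher's exact p = 2.66e-15), which argues against zeros that mark abundant transcripts in general. Probes of one gene or of near-identical globins are not independent, so these p-values are too small. Zeros set where 1 channel is too dim, or where 1 is beyond the scanner's range, may each account for the 56.2% if these transcripts are abundant in 1 tissue only. Spot intensities were not used, so the abundance of these transcripts and of the ribosomal ones was not measured in either channel. No biological explanation was tested.

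Array 3 gave larger ratios than the others. Its SD exceeded the mean SD of arrays 1 and 2 by 12.2% over all listed ratios and by 7.56% on the 10173 common probes, which argues against a different choice of probes as the whole cause. With array medians subtracted, the ratio of array 3 over the mean of arrays 1 and 2 had a median of 1.05 for probes of 1 to 2 log2 units and 1.06 for probes over 3, a difference of 0.0186 that met the bound of 0.05 first set for one constant scale factor. For probes of 1 to 2 units it was 1.09 (bootstrap 95% interval 1.09 to 1.10) on the liver side and 0.982 (0.974 to 0.992) on the spleen side, and this gap of 0.111, examined after that bound was met, argues against one constant scale factor alone. The sides were 1.10 and 0.953 at 0.5 to 1 units and 1.06 and 1.03 at 2 to 3. Over 3 units they were 1.07 (1.06 to 1.08) and 1.06 (1.03 to 1.07), with overlapping intervals. Array medians had been subtracted, so a scale factor with an offset shared by all probes would leave no gap between the sides. The gaps at 0.5 to 1 units (intervals 1.09 to 1.12 and 0.938 to 0.963) and at 1 to 2 argue against it for those probes. A dye, background or biological explanation was not tested.

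Some probes went against their gene or list. Among genes with several called accessions, 26 of 137 expressed sequence tags (19.0%) had a sign opposite to the gene's other accessions. For full-length or RefSeq accessions it was 254 of 2501 (10.2%, two-sided Fisher's exact p = 0.00246, odds ratio 2.07, 95% interval 1.27 to 3.27). Each accession was compared with the median of the gene's others, so 1 conflict can mark both members of a pair. The accessions are therefore not independent, which the p-value and interval do not allow for. The 254 may also include accessions set against a misnamed tag. Wrong gene names of sequence tags may account for part of the pattern. Of 23 genes called against their list's tested direction, 6 (26.1%) rested on sequence tags alone against 35 of 282 (12.4%) called with it (Fisher's exact p = 0.102), which leaves the question open for the lists. Those 6 were Fabp1, Cd3d, H2az1, Psmc3, Ccnd3 (probes called both ways, 1.32 and -1.65) and Scp2, whose 4 tested spots share 1 tag at -2.72 while another probe, left out for its zeros, read 4.57 on array 3. A tissue difference in transcript forms stays open as a biological explanation and was not tested.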

How the results depend on the processing

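The settings with zeros kept and with 1 value per accession were tests chosen after the data were seen. The 66 named genes were followed with array medians subtracted, scaling, each array left out, robust moderation and zeros kept. No call changed sign in these, and the calls lost were of small ratios. They were Canx and Hprt without array 1, Canx, Psme2 and Hprt without array 2, Psme2 without array 3, and Psme2 and Hprt with zeros kept as values. The other settings, treat against 2-fold among them, were not run for single named genes. The count of 8221 probes ranged from 7138 to 8721 when 1 array was left out and was 8222 with array medians subtracted, 8271 with scaling, 8194 with robust moderation, 9566 with ratios on at least 2 arrays, 7901 without the 10% of probes of largest SD, 7657 with zeros kept and 7941 with 1 value per accession. The share higher in liver stayed between 50.3% and 51.8% in these, and was 55.1% with treat. Moved by over 1.5 times by construction were the fit with 1 value per gene (4435 past the threshold, 2254 higher in liver and 2181 in spleen, and with 2-fold 1650, 858 and 792, as fewer units were tested), and treat against 2-fold (2465, with 1357 and 1108, a stricter null). The lists gave 8 calls for liver and 10 for spleen at the preset correlation. With the correlation estimated per list by camera in limma they gave 0 and 0. There 2 had an unadjusted p under 0.05 (cell cycle 0.0303, splicing 0.0424). The estimates for these 2 lists, -0.016 and -0.0014, lay below the preset 0.01. This argues against a larger correlation between genes as the cause of their lost calls. The same held for the macrophage (-0.080), platelet (-0.20), T cell (-0.053) and gluconeogenesis (-0.24) lists. For the other called lists the estimate lay above 0.01, up to 0.76 for granulocytes. The estimates rest on 3 arrays, and the cause was not tested further. The platelet list lost its call with the least variable probe per gene (adjusted p = 0.0807; 0.00421 to 0.352 over the alternatives), and the exocrine pancreas list gained one without array 2 (0.0462) and with zeros kept (0.0348), its highest being 0.512. Robust moderation was not run for the lists, since camera has no such setting. Spearman's rho was 0.949 between arrays 1 and 3 and 0.964 between arrays 2 and 3, and over probes of at least 2-fold r was 0.991 and 0.994. Those probes were chosen by their mean over the same arrays, so their higher r follows at least in part from that choice. Turning the channels on array 1, 2 or 3 left 0 calls in limma, at 2-fold too, against the real 8221 and 3191, with 0, 0 and 1 probes at an unadjusted p under 0.05 against 8345. Only 1 of the 4 splits, the real one, gave as many, and 4 are too few for a share under 0.05. Since the arrays gave close ratios for the same probe, turning 1 of them nearly fixed this outcome in advance. The comparison therefore cannot tell a tissue difference from chance. The test of the ratio against 0 is itself paired, since each array holds both tissues, and with 1 group no further block applies. Signal over background was not used here.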

Other observations

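The tests in this part were chosen after the data were seen, over 63 families of at least 8 tested genes that share the letters of their symbol before the first digit. Of the mitochondrial ribosomal proteins, 26 of 27 Mrpl genes (median 0.93, camera adjusted p = 5.27e-05; adjusted p = 0.835 with an estimated correlation) and 13 of 14 Mrps genes (median 0.87, adjusted p = 0.00487; adjusted p = 0.835 with an estimated correlation) were higher in liver, with Mrpl12 at 2.06 ± 0.07 and Mrps34 at 1.63 ± 0.17. All 11 Timm genes, of protein import into mitochondria, were higher in liver (median 0.82, adjusted p = 0.00492; adjusted p = 0.835 with an estimated correlation), with Timm8a1 at 1.67 ± 0.07. Timm22 and Mrpl15 had probes called in both directions and are counted by their mean. All 8 Abhd genes, most of them hydrolases, were higher in liver (median 1.60, adjusted p = 0.00950; adjusted p = 0.835 with an estimated correlation), with Abhd6 at 2.77 ± 0.11.

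Of 12 Rbm genes, 8 were higher in spleen and 1 in liver (median -0.74, adjusted p = 0.0302), with Rbm3 at -1.79 ± 0.07, and Rbm8a, counted as higher in spleen, had probes called in both directions. The adjusted p with an estimated correlation was 0.835. Of 9 Snhg genes, which host small nucleolar RNAs, 8 were higher in spleen (median -0.74), and the family's adjusted p was 0.0747. Of the 63 families, 7 others passed: Rpl, Rps, Cox, Ndufa, Atp and Srsf, which share genes with the lists above, and Tmem (median 0.43, 46 of 72 higher in liver), with 0.835 for each under an estimated correlation. That adjusted p was shared by families with an unadjusted camera p from 0.0634 (Mrps) to 0.424, so it does not rank them.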
